A study of Mus musculus with 32 samples.

How the data were processed

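Liver RNA from 32 mice was measured, 1 array per mouse, as single replicates numbered within 6 groups: wild type and E2f1 knockout on saline (6 and 6 mice), at 6 h after LPS (4 and 4) and at 20 h after LPS (6 and 6), per the labels. The labels name liver, their extraction protocol lung. Alb (9.19 to 11.2) and Cyp2c29 (4.43 to 8.18, log2 above each array's 75th percentile) argue against lung. The strain (B6x126 F2) stayed open. Sex, dose and deleted part of E2f1 are not given.

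Per the file headers, the authors hybridised Cy3-labelled RNA (1 colour, from 0.5 to 1.0 µg of total RNA per the labels) to Agilent 4x44K mouse arrays and read them with Feature Extraction 10.7.1.1. The deposited scanner files hold an intensity per spot, of which the processed signal was used: the authors' software had subtracted a spatial background, corrected a multiplicative trend and replaced low signals by a surrogate, per the file headers. The deposited processed table holds log2 values of 23916 probes on 32 arrays per the labels; its column medians lie between 8.80 and 8.91, its correlation with the scanner log2 of the same array between 0.980 and 0.991 and its slope between 0.766 and 0.860, and all 32 columns correlated best with their own array. How the authors normalised that table and chose its probes is not given in the sources used here, so it served only as an alternative. The saturation flag is unset throughout, although 0 to 39 spots per array reached 95% of the scanner ceiling; these spots were kept.

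Control spots and spots marked as outliers (84 to 232 per array) were left out, leaving 43379 spots of 41174 probes. Spots of a probe were averaged as log2 signal minus the 75th percentile of the array. Probes well above background on at least 4 arrays were kept (28373), and the brightest probe stood for each gene name, which gave 19226 names with 390 missing values. The names are those of the array; 13536 matched a RefSeq gene of GRCm38 and 1907 of these carry another symbol now. Probe positions are those of the array design on mm9 and were known for 19040 names. The first 3 principal components held 35.2%, 18.7% and 7.86% of the variance.

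Group means were fitted over all 32 arrays with limma 3.58.1 in R 4.3.3, with eBayes, and 11 comparisons were tested two-sided: knockout against wild type on saline and at each time, each time against saline and against the other time in each genotype, and the interaction of genotype and LPS at each time. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 over all genes of a comparison. A log2 change is given with its moderated standard error. Where no array of a group stood well above background, the fold is a lower bound against the background level of that group, and no fold is given where both groups were dim. Where few arrays did, only the log2 change is given, and its size is not exact. Scores along the wild-type responses are projections on the genes called in wild type, so wild-type arrays define them.

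The comparisons, their tests, the gene lists and the alternatives were fixed before the data were examined; what was chosen afterwards is named as such. The 37 lists (694 of 747 genes measured) cover innate immunity, acute-phase and plasma proteins, liver metabolism, stress, cell cycle and E2F genes, sex-biased liver genes and markers of other cell types, lung and pancreas included; some genes stand in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists of a comparison, beside an estimated correlation and fry. Named genes were E2f1, a panel (Saa1, Tnf, Il6, Il1b, Cxcl1, Vegfa, Cyp7a1, Alb), the 6 largest rises and falls among called genes whose groups do not overlap, with clone names left out, the 6 smallest p per sign for the interactions, up to 3 called members of each list with the largest change, and the brightest uncalled member; some of these genes are not reported here. Over-representation near E2f1 was tested with Fisher's exact test in a window of 20 Mb and on the whole of chromosome 2, adjusted over its family.

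The arrays came from 9 slides and 3 scan dates that each hold several groups. Slide, scan date and replicate number were tried as blocks, and comparisons were repeated within each scan date that holds both groups; the third date holds no wild-type saline array. Other alternatives were quantile normalization, median centring, normexp with an offset of 50 followed by quantile normalization, the deposited processed table, no filter and a stricter one, the mean over probes, outlier spots kept, array weights, trend and robust eBayes, only the groups compared, an adjusted p under 0.01, at least a 2-fold change, genes near E2f1 left out, and each replicate left out. A covariate for sex was not run, because sex-linked genes showed no difference in sex between arrays. Leaving out the libraries labelled KO saline replicate 1 and KO LPS 6 h replicate 1 was added after the data were seen. No sample was relabelled.

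The fit was tested on simulated data, with 100 genes of 19226 changed at each size on the measured spread. Between genotypes on saline, 32% of 2-fold and 77% of 4-fold changes were recovered, with 7 false calls; at 6 h it was 19% and 63% with 5; for the interaction at 6 h it was 4% and 45% with 1. Neither the array signal relative to background nor the number of arrays was varied in this test. The noise was drawn independently for each gene and array, without slide effects, correlation between genes or arrays that stand apart. The numbers of false calls therefore need not carry over to the measured arrays.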

Results

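Liver RNA from 32 mice was measured on 1-colour Agilent mouse arrays, with 1 array per mouse. The mice were wild type or homozygous knockouts for E2f1, a transcription factor best known for driving genes of DNA replication. They had been given saline or lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria) systemically, and the series concerns the role of E2F1 in the innate immune response to it. There were 6 wild-type and 6 knockout mice on saline, 4 and 4 at 6 h after LPS, and 6 and 6 at 20 h after LPS. The saline groups are labelled 20 h, so a comparison of 6 h of LPS with saline also differs in the time after injection. The 75th percentile of the signal on an array ranged from 282 to 1138, and 20203 to 28891 spots per array stood well above background. After filtering, 19226 genes were tested in 11 comparisons, and the number of arrays limits their precision.

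E2f1 was read by probes at the 3′ end of the gene, on chromosome 2 at 154385742 to 154386063 (mm9). Which part of the gene is deleted is not given in the sources used here, so this signal is no test of the deletion. On the log2 scale relative to the 75th percentile of the array, its mean was −3.36 ± 1.01 (SD, n = 6) in wild-type saline livers and −3.23 ± 0.81 (SD, n = 6) in knockout saline livers. At 6 h of LPS it was −3.83 ± 0.43 (SD, n = 4) in wild type and −2.30 ± 0.56 (SD, n = 4) in knockouts. At 20 h it was −5.57 ± 0.88 (SD, n = 5, with 3 arrays well above background) and −2.06 ± 1.57 (SD, n = 6). At 20 h E2f1 was higher in knockouts than in wild type (log2 3.51 ± 0.58 SE, adjusted p = 0.00361; 2.10 in its other probe). In wild type E2f1 fell by 2.21 ± 0.58 between saline and 20 h (adjusted p = 0.00386). The difference between genotypes in the E2f1 response was 3.39 ± 0.81 at 20 h (adjusted p = 0.183) and 1.41 ± 0.88 at 6 h (adjusted p = 0.68).

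A pair of knockout libraries stood apart from their labelled groups. Each array was scored along the wild-type response, where 0 is the mean of wild-type saline and 1 the mean of wild-type LPS at that time. On the 6 h score the library labelled KO saline replicate 1 reached 0.885, against −0.0046 to 0.0574 in the other knockout saline arrays. The library labelled KO LPS 6 h replicate 1 reached 0.127, against 0.896 to 0.976 in the others of its group. Both were kept under their labels in the fit of all arrays. The total number of called genes in each comparison is also given without those 2 libraries, an alternative chosen after seeing the data.

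**Figure D1:**
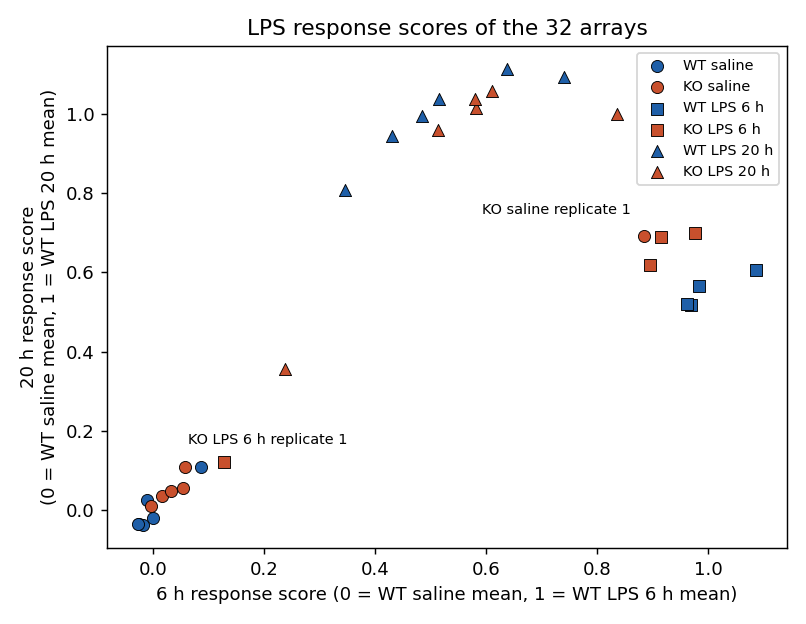
Response score of each of the 32 arrays along the wild-type 6 h response (horizontal) and the wild-type 20 h response (vertical), coloured by group. The library labelled KO saline replicate 1 sits at 0.885 on the 6 h score, among the LPS arrays, and the one labelled KO LPS 6 h replicate 1 at 0.127, near the saline arrays.

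At 6 h of LPS the wild-type liver carried a large interferon and chemokine response beside a loss of cholesterol synthesis and endothelial transcripts (n = 4 LPS and 6 saline). Mx1, an interferon-induced antiviral GTPase, rose 613-fold (log2 9.26 ± 1.32 SE, adjusted p = 1.25e-05). Irg1, which makes itaconate in activated macrophages, rose by 9.13 ± 1.42 on the log2 scale. The chemokines Ccl3, Cxcl10 and Ccl4 rose by 8.85 ± 1.40, 8.83 ± 1.28 and 8.69 ± 1.16, and the interferon-induced Ifit2 by 8.29 ± 1.27. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell (log2 −8.34 ± 1.39, adjusted p = 6e-05; −2.42 in its other probe, with 1 of 4 LPS arrays well above background), and the lipolysis inhibitor G0s2 fell by 5.98 ± 0.83. Cbx2, a Polycomb protein, was at least 20.4-fold lower. The parathyroid hormone receptor Pth1r had a log2 change of −5.66 ± 1.08 and the endothelial transcription factor Sox18 one of −5.35 ± 1.01. The endothelial protocadherin Pcdh12 had −5.42 ± 1.11, in 1 of its 2 probes. Among the cytokines and acute-phase genes chosen in advance, Tnf rose by 5.45 ± 0.95 (adjusted p = 9.97e-05), Il1b by 5.33 ± 0.91 and Il6 by 4.22 ± 0.93. Cxcl1 rose by 5.12 ± 1.30 and Saa1 by 2.73 ± 0.77. Vegfa (0.76 ± 0.33, adjusted p = 0.081) and Alb (0.11 ± 0.27) did not pass.

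Genes were also counted by group; where 1 count is given over all arrays, that adjusted over the list alone was the same. At 6 h in wild type 38 of 39 interferon-stimulated genes rose and none fell (39 adjusted over the list alone), with a median log2 change of 3.97 and adjusted p = 3.33e-23 by camera. Of 34 Toll-like receptor and NF-kB pathway genes 26 rose (28 adjusted over the list alone; median 2.70, adjusted p = 7.95e-14). They were led by the receptors Tlr2 (6.81 ± 1.04) and Cd14 (6.18 ± 1.19) and the NF-kB inhibitor Tnfaip3 (6.18 ± 1.13). Of 23 chemokines 17 rose and 2 fell (17 and 3 adjusted over the list alone; median 4.72, adjusted p = 5.15e-09). Of 17 cytokines 13 rose (15 adjusted over the list alone; median 3.28, adjusted p = 3.01e-09). Ifng rose by 6.95 ± 1.56 and the granulocyte growth factor Csf3 by 6.61 ± 1.54. Of 25 acute-phase proteins 18 rose (19 adjusted over the list alone; median 1.67, adjusted p = 2.46e-08). The siderophore binder Lcn2 had 7.5 ± 1.29 and the metallothionein Mt1 5.22 ± 1.22. Of 19 neutrophil markers 14 rose (15 adjusted over the list alone; median 3.32, adjusted p = 4.53e-07). Retnlg rose by 5.51 ± 0.95 and the granule collagenase Mmp8 by 5.15 ± 1.03. Of 23 cholesterol synthesis genes 19 fell (median −1.52, adjusted p = 5.15e-09). Mvd had −4.20 ± 0.54, Hmgcs1 −2.64 ± 0.60 and Lss −2.50 ± 0.43. None of these calls held with an estimated correlation (adjusted p from 0.3 to 0.403). It came from all arrays (interferon genes 0.874, and 0.675 without those 2 libraries).

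In the same livers 15 of 29 p53 and apoptosis genes rose and 4 fell (18 and 4 adjusted over the list alone; adjusted p = 0.00125). Gadd45b rose by 5.23 ± 1.09 and the inflammatory caspase Casp4 by 4.26 ± 0.74. Of 18 T and NK cell markers 7 rose (adjusted p = 0.0106), led by granzyme Gzmb (4.51 ± 0.76) and Lck (2.71 ± 0.46). Of 19 sinusoidal endothelial markers 9 fell and 2 rose (14 and 2 adjusted over the list alone; median −1.10, adjusted p = 0.0131). Wnt2 fell by 3.90 ± 0.99 and Gpr182 by 3.75 ± 0.73, while Lyve1 rose by 3.02 ± 0.60. Of 31 coagulation and fibrinolysis genes 10 rose (adjusted p = 0.0109), such as the urokinase receptor Plaur (4.84 ± 0.94). Of 13 female-biased liver genes 4 rose (adjusted p = 0.0115), with Cyp3a44 at 2.36 ± 0.46 and the peroxisomal Acot3 at 3.65 ± 1.09. The glucose-6-phosphatase gene G6pc fell by 5.27 ± 0.84 and the clock repressor Nr1d1 by 3.79 ± 0.90. The stress factor Atf3 rose by 5.58 ± 1.07 and the vasodilator Adm by 3.88 ± 0.88. The groups that hold them (gluconeogenesis, circadian clock, unfolded protein response, angiogenesis) had adjusted p of 0.48, 0.732, 0.643 and 0.273. Here too no call held with an estimated correlation (adjusted p from 0.3 to 0.632).

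The remaining gene groups did not pass as sets at 6 h in wild type. Among 35 G1/S genes with E2F sites 5 rose and 11 fell (adjusted p = 0.0932), with the checkpoint kinase Chek1 at 2.35 ± 0.69 and the replication licensing factor Cdt1 at −2.64 ± 0.41. Of 13 E2F and retinoblastoma family genes 2 rose and 2 fell (2 and 3 adjusted over the list alone; adjusted p = 0.756). E2f8 rose by 2.79 ± 0.57, Rbl1 by 2.60 ± 0.54, and E2f2 had −2.15 ± 0.44. Of 21 G2/M genes 1 rose and 6 fell, and of 17 fatty acid synthesis genes 5 fell (7 adjusted over the list alone). Of 21 bile acid genes 4 fell, and of 37 drug-metabolising enzymes 3 rose and 1 fell. Of 16 gluconeogenesis genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), and of 23 urea cycle and amino acid genes 1 rose and 4 fell (1 and 3 adjusted over the list alone). Of 21 unfolded protein response genes 2 rose and 3 fell, and of 21 angiogenesis genes 3 rose and 1 fell. Of 18 circadian genes 2 rose and 3 fell, and of 18 oxidative stress genes 5 rose and 1 fell. Of 25 complement genes 2 rose, of 24 fatty acid oxidation genes 2 rose and of 13 negative acute-phase proteins 1 rose, with 0 in each group adjusted over the list alone. Markers of Kupffer cells (3 rose and 2 fell of 19), stellate cells (2 and 2 of 17), cholangiocytes (1 and 1 of 9) and lung epithelium (2 and 0 of 6, Sftpd by 2.93 ± 0.75) went both ways or little. Male-biased liver genes had 1 fall of 13 and X-inactivation and Y-linked genes 1 rise of 4. No limma call was made, over all genes or adjusted over the list alone, among 8 class II histocompatibility genes (1 at an unadjusted p under 0.05), 10 B cell markers (3), 7 erythroid markers (0) or 5 pancreatic acinar markers (0).

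In all, 5470 genes changed at 6 h in wild type, 2398 upward and 3072 downward. Without those 2 libraries the count was 6174 (2725 upward, 3449 downward), sharing 5465 genes, with 15 of 17 cytokines raised and 12 of 19 sinusoidal markers lower. The calls for Toll-like receptor, chemokine, cytokine and neutrophil genes then held with an estimated correlation (adjusted p = 0.0187, 0.0283, 0.0134 and 0.025), while interferon genes had adjusted p = 0.0668. With slide as a block 4105 genes changed, and the medians of interferon, Toll-like receptor, chemokine, cytokine, acute-phase, neutrophil and cholesterol genes were 4.18, 2.66, 4.63, 3.29, 1.75, 3.32 and −1.60. Within the 2 scan dates that hold both groups, interferon genes had medians of 4.13 and 4.30 and cholesterol genes of −1.76 and −1.36. There 99.7% and 99.6% of called genes kept their sign. Such shares, here and below, are no independent test, since the genes were called on the same arrays. Quantile normalization moved the median of all genes by −0.16 and turned the medians of drug-metabolising (0.28 to −0.07), fatty acid oxidation (0.26 to −0.01), gluconeogenesis (0.22 to −0.14) and oxidative stress genes (0.23 to −0.08).

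At 20 h of LPS the wild-type liver had lost much of its hepatocyte program and had gained neutrophil, acute-phase and unfolded protein response transcripts (n = 6 and 6). The regenerating-islet lectins Reg3b and Reg3g rose from near background (log2 10.99 ± 1.46 SE, adjusted p = 1.63e-06, and 10.50 ± 1.20). Trat1, a T cell receptor adaptor, rose by 8.76 ± 0.82, Lcn2 by 8.06 ± 1.16 and Ch25h, which makes 25-hydroxycholesterol, by 7.72 ± 1.17. Cyp7a1 fell to near background (−9.34 ± 1.24, adjusted p = 1.64e-06; −5.76 in its other probe) and the steroid dehydrogenase Hsd3b5 fell 475-fold (−8.89 ± 0.96). Its relatives changed with it, Hsd3b4 at −7.30, Hsd3b2 at −7.24 and Hsd3b3 at −6.80, and the acyltransferase-like Keg1 stood at −7.48. Tnf (3.16 ± 0.85), Il6 (3.76), Il1b (2.69), Cxcl1 (3.85) and Saa1 (2.30 ± 0.69) were still raised. Vegfa (−0.35, adjusted p = 0.366) and Alb (−0.32, adjusted p = 0.31) did not pass.

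Of 21 bile acid synthesis and transport genes 17 fell at 20 h (median −2.14, adjusted p = 1.2e-10), among them the canalicular export pump Abcb11 (−5.17) and the uptake carrier Slco1b2 (−4.54). Of 37 drug-metabolising enzymes 27 fell and 2 rose (32 and 2 adjusted over the list alone; median −2.19, adjusted p = 3.75e-11), with Cyp2c38 at −4.09 and Cyp3a25 at −3.53. Of 23 urea cycle and amino acid genes 17 fell and 2 rose (adjusted p = 6.09e-09), such as Cth (−3.75). Of 23 cholesterol synthesis genes 19 fell (median −1.60, adjusted p = 1.59e-07). Of 17 fatty acid synthesis genes 15 fell (median −1.97, adjusted p = 3.61e-07), with Elovl6 at −3.55 and the lipogenic regulator Srebf1 at −2.52. Of 25 complement genes 15 fell (adjusted p = 5.92e-05), C9 by 1.92. Male-biased liver genes fell in 10 of 13 (adjusted p = 3.18e-05). Negative acute-phase proteins fell in 7 of 13 (adjusted p = 0.000868; Ttr −3.11, Rbp4 −1.45) and B cell markers in 6 of 10 (7 adjusted over the list alone; adjusted p = 0.0179; Ms4a1 −2.29). Female-biased genes fell in 6 of 13 and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00892). Sinusoidal endothelial markers fell in 10 of 19 and rose in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0104), the lectin Clec4g by 5.46. Of these calls that for bile acid genes held with an estimated correlation (adjusted p = 0.0273), while the others had adjusted p from 0.144 to 0.498.

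Rises at 20 h in wild type were found in 17 of 19 neutrophil markers (median 3.96, adjusted p = 8.15e-09), with the granule protein Ngp at 6.61. Acute-phase proteins rose in 19 of 25 (19, with 1 fall, adjusted over the list alone; median 1.80, adjusted p = 8.28e-07). Interferon-stimulated genes rose in 16 of 39 (median 1.69, adjusted p = 2.88e-06), led by the GTPase Gbp2 (5.87). Of 21 unfolded protein response genes 13 rose (14 adjusted over the list alone; median 1.05, adjusted p = 7.98e-06), with Ddit3 (CHOP) at 2.89 and Asns at 2.79. Of 34 Toll-like receptor genes 15 rose (17 adjusted over the list alone; adjusted p = 2.32e-05), Cd14 by 7.30 and the signalling brake Irak3 by 5.07. Chemokines rose in 15 of 23 and fell in 3 (16 and 5 adjusted over the list alone; adjusted p = 0.00031). The p53 and apoptosis genes rose in 15 of 29 and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.000356; the cell cycle inhibitor Cdkn1a 5.39). Cytokines rose in 10 of 17 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00482). Coagulation genes went both ways, 8 up and 14 down of 31 (adjusted p = 0.0314; Plaur 4.93, prekallikrein Klkb1 −4.74). Kupffer cell markers had 4 rises and 10 falls of 19 (adjusted p = 0.0774; the complement receptor Vsig4 −4.19, Cd5l −3.93, the iron exporter Slc40a1 −4.23). Stellate cell markers had 3 and 8 of 17 (3 and 9 adjusted over the list alone; adjusted p = 0.0793; Colec11 −3.81). Gluconeogenesis genes had 3 and 6 of 16 (4 and 7 adjusted over the list alone; adjusted p = 0.0793; the glucose transporter Slc2a2 −5.16). Among 35 G1/S genes with E2F sites 5 rose and 7 fell (adjusted p = 0.729; thymidine kinase Tk1 −3.78, Mcm10 −3.54). No call for these rises held with an estimated correlation (adjusted p from 0.301 to 0.524).

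A total of 7030 genes changed at 20 h in wild type, 3172 upward and 3858 downward. Once those 2 libraries were left out it was 7932 (3639 and 4293), sharing 7025, with 30 of 39 interferon-stimulated and 23 of 34 Toll-like receptor genes raised. The calls for the neutrophil rise and the fatty acid synthesis fall then held with an estimated correlation (adjusted p = 0.0189 and 0.0254), as did that for bile acid genes (adjusted p = 0.0189). Under a slide block 6929 genes changed. The medians were then −2.04 for bile acid, −2.13 for drug-metabolising, −1.74 for urea cycle, −1.49 for cholesterol and −2.03 for fatty acid synthesis genes. They were 3.95 for neutrophil, 1.95 for acute-phase, 1.90 for interferon and 1.09 for unfolded protein response genes. Within the 2 scan dates that hold both groups the bile acid medians were −2.06 and −2.68 and 100% and 99.9% of called genes kept their sign.

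Between 6 h and 20 h the wild-type liver lost interferon and drug-metabolising transcripts and gained unfolded protein response transcripts (n = 4 and 6). The lipolysis inhibitor G0s2, low at 6 h, came back by 6.30 ± 0.83, Olig1 rose by 6.14, the p53 target Phlda3 by 5.18 and Trat1 at least 117-fold. The interferon-induced Cmpk2 and Ifit1 changed by −6.79 and −6.77, the collagenase Mmp13 by −7.04, Hsd3b5 by −7.13 and Keg1 by −7.11. Vegfa was lower by −1.11 ± 0.33 (adjusted p = 0.0088) and Il1b by −2.64 ± 0.91 (adjusted p = 0.0247). Tnf (−2.29, adjusted p = 0.0619) and Il6 (−0.46, adjusted p = 0.733) did not pass. Drug-metabolising enzymes fell in 30 of 37 (31 with 1 rise adjusted over the list alone; median −2.36, adjusted p = 1.92e-13). Interferon-stimulated genes fell in 21 of 39 (22 adjusted over the list alone; median −2.19, adjusted p = 3.47e-07) and bile acid genes in 12 of 21 (adjusted p = 3.47e-07). Falls came in 7 of 17 cytokines (8 adjusted over the list alone; adjusted p = 0.00559) and 9 of 13 female-biased liver genes (adjusted p = 3.28e-05). They came also in 9 of 13 male-biased liver genes (10 adjusted over the list alone; adjusted p = 0.000111) and 7 of 13 negative acute-phase proteins (11 adjusted over the list alone; adjusted p = 0.000209). Of 21 unfolded protein response genes 12 rose and 1 fell (adjusted p = 0.000886), Ddit3 by 3.05 and the chaperone cofactor Sdf2l1 by 3.04. Of 18 oxidative stress genes 9 fell and 2 rose (10 and 2 adjusted over the list alone; median −0.72, adjusted p = 0.0336). Toll-like receptor genes fell in 11 of 34 (median −1.15, adjusted p = 0.000985), chemokines in 9 of 23 with 1 rise (adjusted p = 0.0251) and class II genes in 2 of 8 (3 adjusted over the list alone; adjusted p = 0.0481). B cell markers fell beside them in 6 of 10 (median −1.27, adjusted p = 0.00903). Clock genes Arntl (3.04) and Per2 (1.85) were among 4 rises of 18 (adjusted p = 0.317). No group call between the times held with an estimated correlation (adjusted p from 0.0661 to 0.613).

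Of the 6578 genes that changed between 6 h and 20 h in wild type, 3273 were higher and 3305 lower at 20 h. Without those 2 libraries it was 7475 (3701 and 3774), sharing 6570. With slide as a block it was 5345, with medians of −1.92 for drug-metabolising and −2.09 for interferon genes. Within the scan dates 99.8%, 99.1% and 97.6% kept their sign, and drug-metabolising genes had medians of −2.45, −1.86 and −1.75. Quantile normalization gave 4182 higher and 2752 lower, moved the median of all genes from −0.08 to 0.11 and turned the acute-phase median from −0.22 to 0.33.

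**Figure D2:**
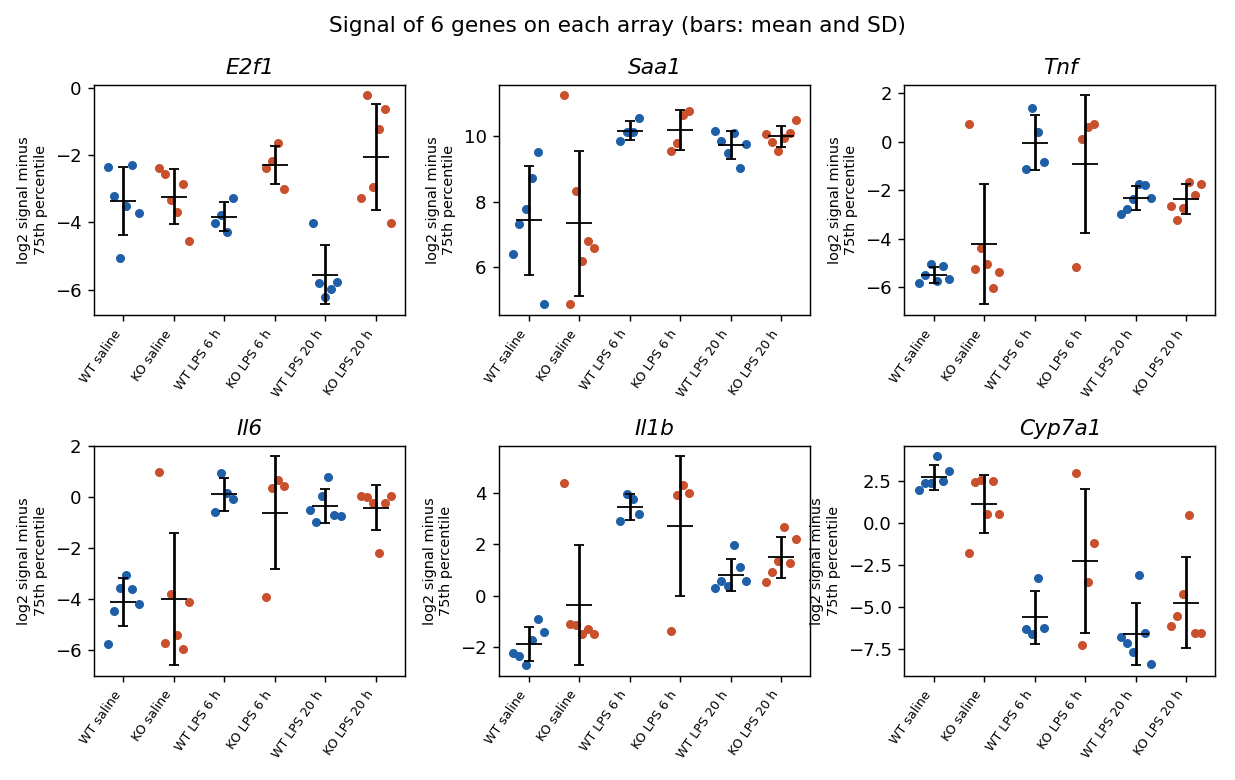
Log2 signal relative to the 75th percentile of the array for E2f1, Saa1, Tnf, Il6, Il1b and Cyp7a1 on each of the 32 arrays, with the mean and SD of each group; E2f1 has no value on 1 array, of the WT LPS 20 h group. Tnf rose by 5.45 and Cyp7a1 fell by 8.34 on the log2 scale at 6 h in wild type, and E2f1 was higher in knockouts at 20 h by 3.51.

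In knockout livers at 6 h the same kinds of genes rose (n = 4 LPS and 6 saline). The SD of the 6 h score was 0.403 in this group and 0.0418 without KO LPS 6 h replicate 1, against 0.0575 in wild type. Trat1 rose (log2 5.50 ± 0.92 SE, adjusted p = 0.0152). Bmp2k rose by 1.49, Akap13 by 1.32, Rbms1 by 1.20 and Wipf3 by 1.17. Lad1 was at least 2.92-fold and Ptpdc1 at least 2.24-fold lower. Arhgef10 fell by 1.79, Zdhhc1 by 1.28, the tubulin Tubb2a by 1.21, and Mical3 by 1.23 in 1 of its 2 probes. Il6 (3.39 ± 0.93, adjusted p = 0.0483) and Saa1 (2.84 ± 0.77, adjusted p = 0.047) passed. Tnf (3.30 ± 0.95, adjusted p = 0.0534), Il1b (3.08, adjusted p = 0.0584), Cxcl1 (4.16, adjusted p = 0.0672) and Cyp7a1 (−3.38 ± 1.39, adjusted p = 0.149) did not. Once those 2 libraries were left out the same changes were 5.49 for Il6 and 3.83 for Saa1. They were Tnf 5.704 ± 0.44 (adjusted p = 6.24e-10), Il1b 5.38, Cxcl1 6.80 and Cyp7a1 −5.71 ± 1.31 (adjusted p = 0.00137).

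Interferon-stimulated genes rose in 20 of 39 in knockouts at 6 h (39 adjusted over the list alone; median 2.99, adjusted p = 9.44e-28). Ifit1 rose by 4.85 and Rsad2 by 4.81. Neutrophil markers rose in 12 of 19 (17 adjusted over the list alone; median 3.11, adjusted p = 1.47e-15). Ngp rose by 5.81 and S100a9 by 4.66. Acute-phase proteins rose in 10 of 25 (19 adjusted over the list alone; adjusted p = 7.52e-14) and Toll-like receptor genes in 7 of 34 (22 adjusted over the list alone; adjusted p = 6.76e-13). Chemokines rose in 9 of 23 (14 with 1 fall adjusted over the list alone; adjusted p = 9.44e-10) and cytokines in 2 of 17 (12 adjusted over the list alone; adjusted p = 3.52e-09). Their adjusted p with an estimated correlation was 0.269 to 0.276. Without those 2 libraries the rises were 39, 17, 21, 27, 18 and 14 in that order. Each of these calls held with an estimated correlation (adjusted p = 0.0338, 0.00311, 0.0314, 0.0104, 0.0202 and 0.00587). The p53 and apoptosis genes rose in 2 of 29 (14 with 2 falls adjusted over the list alone; adjusted p = 1.51e-06, and adjusted p = 0.34 with an estimated correlation). Without those 2 libraries 19 rose and 2 fell (adjusted p = 0.0462 with an estimated correlation). Under a slide block the interferon median was 2.89 and the neutrophil median 2.93. Within scan dates interferon genes had medians of 4.75 and 4.95, and −2.09 on the date that holds both libraries.

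The count of genes changed at 6 h in knockouts was 502 (304 upward, 198 downward) with all arrays and 5597 (2469 and 3128) without those 2 libraries, sharing 502. With slide as a block limma called 0 genes (3911 at an unadjusted p under 0.05). Without KO LPS 6 h replicate 1 alone the count was 3885 and without KO saline replicate 1 alone 3542. It was 0 to 2 with any other single library of these groups left out. The 0 counts came without KO LPS 6 h replicate 2 or 3, where limma had 2966 and 2401 genes at an unadjusted p under 0.05. On the 3 scan dates 100%, 100% and 27.5% of called genes kept their sign. Median centring gave 340 upward and 85 downward with the median of all genes at 0.10 instead of −0.02.

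At 20 h of LPS the knockout liver, like the wild type, had more neutrophil and acute-phase transcripts and fewer hepatocyte enzyme transcripts (n = 6 and 6). Reg3g rose by log2 9.69 ± 1.20 (SE, adjusted p = 3.33e-06), Trat1 by 8.08 ± 0.82, and the dynein Dnahc2 by 6.37. The crystallin Crybb3 rose by 5.91, the alternative-activation marker Retnla by 5.85 and Chi3l4 by 5.12. Aldehyde oxidase Aox3 changed by −5.02, the Wnt inactivator Notum by −4.95, Agxt2l1 by −4.77, the steroid reductase Srd5a1 by −4.70, Abca8a by −4.53 and Itga8 by −4.52 in 2 of its 3 probes. Cyp7a1 fell by 5.89 ± 1.24 (adjusted p = 0.000875; −6.94 without KO LPS 20 h replicate 4 and −6.47 without those 2 libraries), and Il6 (3.58 ± 0.83) and Saa1 (2.65 ± 0.69) rose. Tnf (1.86, adjusted p = 0.107; 2.85 and adjusted p = 1.33e-06 without those 2 libraries) did not pass. Neutrophil markers rose in 17 of 19 (median 3.25, adjusted p = 2.89e-11) and acute-phase proteins in 19 of 25 (median 1.95, adjusted p = 6.31e-11). Interferon-stimulated genes rose in 16 of 39 (19 adjusted over the list alone; adjusted p = 3.07e-08). Drug-metabolising enzymes fell in 27 of 37 and rose in 2 (median −1.76, adjusted p = 3.17e-11). Bile acid genes fell in 13 of 21 (14 adjusted over the list alone; adjusted p = 1.3e-07) and cholesterol synthesis genes in 7 of 23 (adjusted p = 0.0422). None of the calls at 20 h held with an estimated correlation (adjusted p from 0.156 to 0.665). The neutrophil call did once those 2 libraries were left out (median 4.29, adjusted p = 0.0035 with an estimated correlation), and 37 interferon-stimulated genes rose and 13 cholesterol synthesis genes fell.

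At 20 h 5053 genes changed in knockouts (2241 upward, 2812 downward), and 6696 (3068 and 3628) without those 2 libraries, sharing 4821. Under a slide block it was 5536, where the medians were 3.47 for neutrophil and −1.78 for drug-metabolising genes. Within scan dates 99.8%, 99.6% and 99.8% kept their sign, and the drug-metabolising medians were −2.40, −1.44 and −1.39. Median centring gave 2758 upward and 1970 downward, with the median of all genes at 0.06 instead of −0.09.

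From 6 h to 20 h in knockouts (n = 4 and 6), Retnla rose by 4.89, the cytidine deaminase Cda by 3.82, the vitamin D receptor Vdr by 3.17 and Dnahc2 by 3.23. Thyroglobulin Tg and Tppp3 were at least 4.52-fold and 3.26-fold higher. Aox3 changed by −4.92, Upp2 by −4.63, Akr1c6 by −4.47, Akr1c20 by −4.26, Abca8a by −4.24 and Srd5a1 by −4.35 in 2 of its 3 probes. Vegfa changed by −0.97 ± 0.33 (adjusted p = 0.0407). Drug-metabolising enzymes fell in 26 of 37 and rose in 1 (28 and 1 adjusted over the list alone; median −1.72, adjusted p = 1.69e-15). Bile acid genes fell in 11 of 21 (14 adjusted over the list alone; adjusted p = 6.23e-07). Interferon-stimulated genes fell in 3 of 39 (1 adjusted over the list alone; adjusted p = 0.00563), and in 25 without those 2 libraries. With an estimated correlation these groups had adjusted p from 0.1 to 0.912. In all 2992 genes changed (1391 higher, 1601 lower), and 4291 (2204 and 2087) without those 2 libraries, sharing 2598. With slide as a block it was 2311, with a drug-metabolising median of −1.45. Leaving out KO LPS 6 h replicate 3 or 4 gave 1866 and 1802. On the 3 scan dates 99.7%, 99.6% and 88.9% kept their sign. Normexp with quantile normalization gave 1833 higher and 1257 lower, and the deposited processed values 1821 and 1252.

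**Figure D3:**
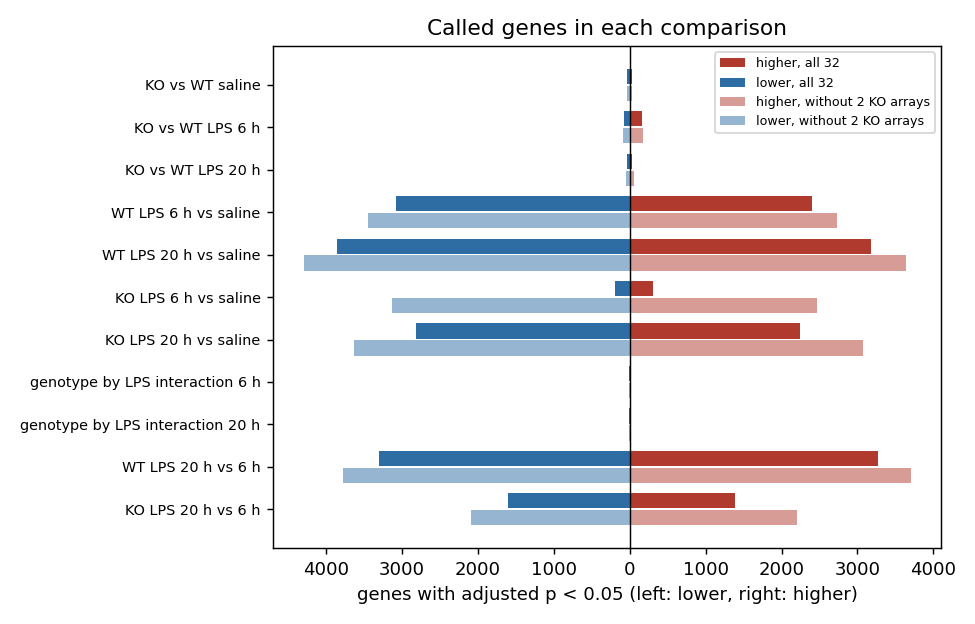
Number of genes called in each of the 11 comparisons, higher to the right and lower to the left, with all 32 arrays and without the 2 knockout libraries that stood apart. Wild type at 6 h had 5470 called genes, and knockouts at 6 h had 502 with all arrays and 5597 without those 2.

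The comparison of genotypes on saline asks what differed between them without LPS (n = 6 and 6). Adamts13, the protease that cleaves von Willebrand factor, was at least 8.11-fold higher in knockouts (log2 5.07 ± 0.53 SE, adjusted p = 3.18e-06) and near background in wild type. The phospholipid flippase Atp10d was 7.88-fold higher (2.98 ± 0.61, adjusted p = 0.0184) and Syngr4 6.17-fold (2.62 ± 0.34, adjusted p = 7.83e-05). The acyltransferase Mogat1 was higher by 1.64 ± 0.28 and asparagine synthetase Asns by 2.29 ± 0.53 (adjusted p = 0.047, a call lost without those 2 libraries). The carotene-cleaving enzyme Bcmo1 was lower by −4.16 ± 0.88 (adjusted p = 0.025), the chemokine Cxcl14 by −3.44 ± 0.68 and Otog by −3.14 ± 0.58. The macrophage lectin Cd209f was lower by −3.07 ± 0.51, Zc3h12d by −2.77 ± 0.53 and the smooth muscle phosphatase inhibitor Ppp1r14a by −2.75 ± 0.62. No limma call was made among 35 G1/S genes with E2F sites (2 at an unadjusted p under 0.05) or among 13 E2F and retinoblastoma family genes (1 unadjusted), with none adjusted over the list alone in either.

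As a set, class II histocompatibility genes were higher in saline knockouts, where 0 of 8 passed over all genes and 5 adjusted over the list alone (median 0.96, adjusted p = 1.11e-06). T and NK cell markers moved with them, with 0 of 18 passing either way (median 0.67, adjusted p = 3.76e-06), and had a median of 0.38 without those 2 libraries. So did 13 female-biased liver genes with 0 passing either way (median 0.80, adjusted p = 0.00233). Cholesterol synthesis genes were lower with 0 of 23 passing either way (median −0.58, adjusted p = 5.49e-08). Their median was −0.26 without those 2 libraries and 0.23 and −0.79 on the scan dates that hold both groups. Interferon-stimulated genes were higher with 0 of 39 passing (median 0.43, adjusted p = 0.00711). Without those 2 libraries their camera call turned over to lower (median −0.28, adjusted p = 0.0241, and adjusted p = 0.955 with an estimated correlation). Unfolded protein response genes were higher with 1 of 21 passing, Asns (median 0.45, adjusted p = 0.00251). Their median was 0.21 (adjusted p = 0.127) without those 2 libraries and 0.53 and −0.21 on the scan dates. With an estimated correlation these groups had adjusted p from 0.168 to 0.847, and by fry from 0.109 to 0.759. Under a slide block the medians were 0.88 for class II, 0.58 for T and NK, 0.79 for female-biased and −0.61 for cholesterol genes. In all 65 genes differed, 26 higher and 39 lower. It was 70 (33 and 37) without those 2 libraries, sharing 53, and 39 with slide as a block, sharing 33. All called genes, chosen on the same arrays, kept their sign on the 2 scan dates that hold both groups. Normexp with quantile normalization gave 23 higher and 72 lower, and the deposited processed values 26 and 67. Leaving out WT saline replicate 1, 2, 3 or 4 gave 37, 41, 41 and 37. Leaving out KO saline replicate 3, 4 or 5 gave 39, 42 and 42.

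At 6 h of LPS 3 of 29 p53 and apoptosis genes were higher in knockout than in wild-type livers (n = 4 and 4), and the list did not pass as a set (adjusted p = 0.506). The BH3-only killer gene Bbc3 (PUMA) was higher by 2.13 ± 0.36 (SE, adjusted p = 0.00247). The other 2, Phlda3 and Sesn2, were higher by 2.53 ± 0.56 and 1.998 ± 0.45 (adjusted p = 0.0196 and 0.0204). The repressor Hic1 and the sulfotransferase Chst12 were higher by 2.84 ± 0.48 and 2.51 ± 0.35 (adjusted p = 0.00247 and 0.000432). The helicase subunit Mcm3 was higher by 1.54 ± 0.33 (adjusted p = 0.0137, a call lost without those 2 libraries). So were Nhlrc1 by 2.66, Pla2g4b by 2.55, and Trat1 at least 16.8-fold. The melanin enzyme Dct was lower by −7.41 ± 1.55 (adjusted p = 0.0135), Cenpl, a kinetochore gene, by −2.67, and Olfr1215 by −2.65. Fut10 and Adamts6 were lower by −2.62 each, Snap91 at least 1.96-fold, tissue factor F3 by −1.82 (adjusted p = 0.0385) and Il15 by −1.10 (adjusted p = 0.0304). None of Tnf (−0.89 ± 1.04), Il6 (−0.72 ± 1.02), Il1b (−0.74 ± 1.00), Cxcl1 (−1.17 ± 1.42), Saa1 (0.02 ± 0.84), Vegfa (0.36 ± 0.36) or Cyp7a1 (3.38 ± 1.52) passed.

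As groups at 6 h, unfolded protein response genes were higher in knockouts, with 1 of 21 passing over all genes and 3 adjusted over the list alone (median 0.69, adjusted p = 0.000228). Their median was 0.42 with slide as a block and 0.84, 0.72 and −0.47 on the 3 scan dates. The passing gene was Sdf2l1 (2.39 ± 0.50, adjusted p = 0.0135). The p53 and apoptosis genes had a median of −0.15 against an upward test. Leaving out those 2 libraries, 4 were higher and 6 adjusted over the list alone (median 0.15, adjusted p = 0.0031, and adjusted p = 0.642 with an estimated correlation). Of 35 G1/S genes with E2F sites 1 was higher and 3 adjusted over the list alone (median 0.26, adjusted p = 0.0151). The set no longer passed without those 2 libraries, with 0 and 2 genes (median 0.02, adjusted p = 0.225). Interferon-stimulated genes had 0 of 39 passing and a median of −0.85 (adjusted p = 0.000501), which was 0.21 without those 2 libraries and −0.13, 0.20 and −4.40 on the 3 scan dates. Toll-like receptor genes (median −0.68, adjusted p = 0.001), chemokines (−0.77, adjusted p = 0.0193) and cytokines (−0.72, adjusted p = 0.00691) were lower as sets, with 0, 0 and 1 genes passing and 0, 0 and 3 adjusted over the list alone. Their medians were 0.02, 0.00 and 0.25 without those 2 libraries. Cholesterol synthesis genes were higher with 1 of 23 passing and 2 adjusted over the list alone (median 0.41, adjusted p = 0.00201; 0.23 and adjusted p = 0.0967 without those 2 libraries). Fatty acid oxidation genes were lower with 0 of 24 passing either way (median −0.31, adjusted p = 0.016). With an estimated correlation the groups that passed had adjusted p from 0.93 to 0.961.

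Without those 2 libraries neutrophil markers were higher as a set in knockouts at 6 h (median 1.66, adjusted p = 2.86e-12). Of 19 markers 2 passed over all genes and 11 adjusted over the list alone. The call held with an estimated correlation (adjusted p = 0.0253). The gelatinase Mmp9 (2.64 ± 0.49, adjusted p = 0.00614) and Chi3l3 (2.999 ± 0.61, adjusted p = 0.0108) passed. The granule genes Ngp (2.51 ± 0.72, adjusted p = 0.0805), Ltf (2.55 ± 0.67, adjusted p = 0.0509), Camp (2.22 ± 0.69), S100a8 (1.70 ± 0.50) and S100a9 (1.66 ± 0.50) did not. The unfolded protein response group then had a median of 0.81 (adjusted p = 2.71e-11, and 0.0253 with an estimated correlation). Of its 21 genes 3 passed and 10 adjusted over the list alone. Its passing genes were Sdf2l1 (2.88 ± 0.45), Ddit3 (2.49 ± 0.39, adjusted p = 0.00154) and Creld2 (2.06 ± 0.49, adjusted p = 0.0281). Still without those 2 libraries, the neutrophil and unfolded protein medians were 1.22 and 0.75 with slide as a block and 1.45 and 0.82 with scan date as a block. They were 1.07 to 1.87 and 0.64 to 1.02 over the 4 other scalings. Leaving out each further array of these groups gave neutrophil medians of 1.40 to 1.89. The call with an estimated correlation was lost without KO LPS 6 h replicate 2 (adjusted p = 0.178, and 0.169 for the unfolded protein response) and without WT LPS 6 h replicate 4 (0.113 and 0.0986). With all arrays the neutrophil median was 0.53 (adjusted p = 0.19) with limma calling 0 of 19 (2 at an unadjusted p under 0.05). It was −0.04 with slide as a block and 1.69, 1.78 and −2.68 on the 3 scan dates, the last of which holds both libraries. Genes named here outside the fixed rule were chosen after their values were seen.

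A total of 242 genes differed between genotypes at 6 h, 169 higher and 73 lower in knockouts. Once those 2 libraries were left out it was 257 (173 and 84), sharing 142, and with slide as a block 62, sharing 49. Leaving out WT LPS 6 h replicate 1, 2 or 4 gave 77, 140 and 156, and leaving out KO LPS 6 h replicate 4 gave 126. On the 3 scan dates 99.2%, 99.6% and 100% of called genes kept their sign. Median centring gave 220 higher and 51 lower, with the median of all genes at 0.12 instead of −0.02, and normexp with quantile normalization gave 122 and 97.

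At 20 h of LPS the genes that differed beside E2f1 included 3 Cyp2b enzymes, which metabolise foreign compounds (n = 6 and 6). Cyp2b10 was higher in knockouts by 3.002 ± 0.65 (SE, adjusted p = 0.028) and Cyp2b9 by 2.99 ± 0.63 (adjusted p = 0.0222). Cyp2b13 was higher by 3.08 ± 0.64 (adjusted p = 0.0208), in 1 of its 2 probes. Car10 was at least 1.79-fold higher, Prm1 higher by 2.11, the potassium channel gene Kcnh2 by 2.08 and progranulin Grn by 1.57. The interferon-induced GTPase Gbp1 (now Gbp2b) was at least 102-fold lower (−7.33 ± 1.34, adjusted p = 0.00782) and Dct at least 21.2-fold lower. Moxd1 was lower by −4.48, Tiam2 by −3.71, the lipoprotein receptor Vldlr by −3.13 and Fxyd6 by −2.68. Of 37 drug-metabolising enzymes 3 were higher (adjusted p = 0.00123) and of 13 female-biased genes 2 were higher (adjusted p = 0.00948). Of 13 E2F and retinoblastoma genes 1 was higher, E2f1 itself (3 with 1 lower adjusted over the list alone; adjusted p = 0.0318). Of 35 G1/S genes with E2F sites again E2f1 alone passed (2 with 1 lower adjusted over the list alone; adjusted p = 0.0603). Coagulation genes had 0 of 31 passing and 1 adjusted over the list alone (median 0.30, adjusted p = 2.45e-07). Complement (median 0.40), urea cycle (0.40) and B cell genes (0.57) had camera adjusted p of 0.000123, 0.000546 and 0.00123, with 0, 0 and 3 genes passing adjusted over the list alone. Sets of G2/M, Kupffer, T and NK, acute-phase, bile acid, cholesterol, gluconeogenesis, interferon and class II genes were higher too (medians 0.26 to 0.73, adjusted p from 0.00123 to 0.0266). None of their genes passed over all genes, and 1 bile acid gene did adjusted over the list alone. Unfolded protein response genes were lower in knockouts at 20 h, with 0 of 21 passing either way (median −0.37, adjusted p = 0.00123). As a set they were higher at 6 h, and on saline only with those 2 libraries included (camera adjusted p = 0.127 without them). With an estimated correlation the groups that passed had adjusted p from 0.3 to 0.724. The calls for B cell, coagulation, complement, urea cycle and unfolded protein response genes stood with each array of the 2 groups left out in turn. Those for G2/M, Kupffer, T and NK, bile acid, cholesterol and class II genes were lost without KO LPS 20 h replicate 4 (adjusted p from 0.0605 to 0.742), whose 20 h score was 0.355 against 0.960 to 1.06 in its group. Those for drug-metabolising, female-biased, acute-phase, gluconeogenesis and interferon genes were lost without KO LPS 20 h replicate 6 (adjusted p from 0.0942 to 0.436). Replicate 6 stood apart too, with a 6 h score of 0.835 against 0.237 to 0.610 in its group. Its Cyp2c29 signal was 7.17 against 4.43 to 5.44. No fit left out both replicates 4 and 6. The call stood in 8 of 12 fits for Kupffer genes, 9 for interferon genes and 10 each for drug-metabolising, acute-phase and gluconeogenesis genes. That for E2F and retinoblastoma genes stood in 7 of 12 such fits. The urea cycle median was 0.20 without replicate 4 and 0.16 without replicate 6, and the B cell median 0.34 without replicate 4.

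At 20 h 62 genes differed between genotypes (32 higher, 30 lower), 100 (57 and 43) without those 2 libraries, sharing 62, and 28 with slide as a block, sharing 24. Without KO LPS 20 h replicate 3 it was 33 and without WT LPS 20 h replicate 5 it was 37. On the scan dates 100%, 100% and 98.4% of called genes kept their sign. With slide as a block the medians were 0.25 for coagulation, 0.28 for complement, 0.41 for urea cycle and 0.57 for B cell genes. Within scan dates the coagulation medians were 0.26, 0.22 and 0.66 and the complement medians −0.05, 0.28 and 0.29. Genes within 20 Mb of E2f1 were not over-represented among the genotype differences (saline odds ratio 1.62, 95% interval 0.191 to 6.14, Fisher's exact two-sided p = 0.357; 6 h 1.08, exact p = 0.811; 20 h 1.70, exact p = 0.336). Among them Rprd1b was lower in saline (−2.15) and at 20 h (−1.82).

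The interaction asks whether the response to LPS differed between genotypes. At 6 h (n = 4 to 6 per group) the small GTPase gene Rab40c, at 2.15 in wild-type saline and 0.69 in wild-type LPS but 2.11 and 1.98 in knockouts, differed by 1.34 ± 0.23 (SE, adjusted p = 0.00946). The Rab GTPase regulator Tbc1d2 (2.33 ± 0.39), Gtlf3b (1.87 ± 0.32) and Chst12 (2.64 ± 0.45, all adjusted p = 0.00946) responded more positively in knockouts. So did the anti-proliferative Tob1 (2.38 ± 0.46), the death-effector gene Dedd2 (2.89 ± 0.56) and Bbc3 (2.34 ± 0.46, all adjusted p = 0.0232). The antiviral deaminase Apobec3 (−3.23 ± 0.62 in 1 of its 2 probes, adjusted p = 0.0232), Ltbp1 (−2.82 ± 0.55), the Notch ligand Dll1 (−2.77 ± 0.52), Zfp296 (−2.62 ± 0.49), Zufsp (−2.77 ± 0.55) and Tanc1 (−1.60 ± 0.32) responded more negatively. Tnf (−2.15 ± 1.35), Il6 (−0.83) and Cyp7a1 (4.96 ± 1.96) did not pass (adjusted p = 0.682, 0.891 and 0.412). Without those 2 libraries Tnf and Il6 rose more in knockouts than in wild type, and Cyp7a1 fell less. Cholesterol synthesis genes had an interaction median of 1.13 with 0 of 23 passing and 3 adjusted over the list alone (adjusted p = 3.11e-09). Class II genes had −1.66 with 0 of 8 (adjusted p = 1.27e-05) and female-biased genes −1.50 with 0 of 13 (adjusted p = 0.000314). They had 6 and 3 genes lower adjusted over the list alone. T and NK cell markers moved with the class II genes, with 0 of 18 passing either way (median −0.56, adjusted p = 0.00636; −0.38 and adjusted p = 0.111 without those 2 libraries). Under a slide block the cholesterol, class II and female-biased medians were 1.16, −1.17 and −1.45, and without those 2 libraries 0.55, −1.89 and −1.62. With an estimated correlation these groups had adjusted p from 0.15 to 0.578. Interferon, Toll-like receptor, chemokine and cytokine genes had interaction medians of −1.26, −1.10, −1.89 and −1.21 (adjusted p = 1.73e-06, 2.11e-06, 0.000771 and 0.000314). They had adjusted p from 0.71 to 0.843 with an estimated correlation, and without those 2 libraries medians of 0.43, 0.18, −0.14 and 0.36. None of their genes passed over all genes, and 3 cytokines were lower adjusted over the list alone.

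The interaction count at 6 h was 24 (11 positive, 13 negative), 29 (17 and 12) without those 2 libraries, sharing 13, and 7 with slide as a block, sharing 4. Leaving out WT LPS 6 h replicate 4 or KO LPS 6 h replicate 1 gave 8 each. Without those 2 libraries the neutrophil group had an interaction median of 1.71 (adjusted p = 2.26e-13, and 0.034 with an estimated correlation). It was then 1.24 with slide as a block. The unfolded protein response group had 0.84 with 0 of 21 passing and 3 adjusted over the list alone (adjusted p = 1.88e-06). Its call did not hold with an estimated correlation (adjusted p = 0.141), and did in 2 of 18 fits that each left out a further array. Of the neutrophil genes Chi3l3 passed (3.74 ± 0.78, adjusted p = 0.0357). The neutrophil call with an estimated correlation was lost without KO LPS 6 h replicate 2 (adjusted p = 0.206), WT LPS 6 h replicate 4 (0.145), or KO saline replicate 2 (0.067) or 5 (0.066). Median centring gave 18 positive and 4 negative, with the median of all genes at 0.27, quantile normalization 18 and 12, and normexp with quantile normalization 8 and 15.

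At 20 h the sorting receptor Sorl1 (3.40 ± 0.49, adjusted p = 0.00218), Fras1 (2.62 ± 0.43, adjusted p = 0.00567) and the Golgi mannosidase Man2a2 (1.38 ± 0.26 in 3 of its 4 probes, adjusted p = 0.0353) responded more positively in knockouts. Adamts13 responded more negatively (−4.99 ± 0.75, adjusted p = 0.00245). Mean Adamts13 signal was −7.003 in wild-type saline and −3.75 at 20 h, against −1.93 and −3.68 in knockouts. The sizes for Sorl1, Fras1 and Adamts13 are not exact, because no array stood well above background for the first 2 in knockout saline livers and wild-type livers at 20 h, or for Adamts13 in wild-type saline. No list had a member passing over all genes. Cholesterol synthesis genes had a median of 0.92 with 1 adjusted over the list alone (adjusted p = 2.01e-10). Bile acid genes had 0.58 with 2 adjusted over the list alone (adjusted p = 9.1e-06). Unfolded protein response genes had −0.82 with 0 of 21 passing either way (adjusted p = 2.91e-06), and −0.45 without those 2 libraries. These groups had adjusted p of 0.469, 0.39 and 0.46 with an estimated correlation. With slide as a block these medians were 0.71, 0.42 and −0.81. The count was 8 (3 positive, 5 negative), 11 (3 and 8) without those 2 libraries, sharing 7, and 1 with slide as a block. Leaving out KO LPS 20 h replicate 1 gave 14, and leaving out most other single libraries, of each group, gave 4 or 5. Median centring gave 3 and 2, with the median of all genes at 0.20, and the deposited processed values gave 0 and 1.

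Across genes the responses of the genotypes ran together, though genes are not independent replicates and each genotype was set against its own saline mice. At 6 h Pearson's r over 19226 genes was 0.809 and Spearman's rho 0.697. Of the genes called in wild type 94.5% had the same sign in knockouts, with 457 called in both in the same direction and 0 in opposite directions, and 4008 and 16 without those 2 libraries. The slope through 0 of the knockout on the wild-type response, over genes called in wild type, was 0.555, and 0.909 without those 2 libraries. Choosing genes on the wild-type response lowers such a slope, and its value in the absence of a genotype difference was not computed. At 20 h r was 0.863, rho 0.789, the share of same sign 96.6% and the slope 0.747, and 0.858 without those 2 libraries, with 4021 genes called in both in the same direction and 3 in opposite directions, and 5248 and 12 without those 2 libraries.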

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

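The tests of an exchange of libraries, of scan date or slide, of donor DNA next to E2f1 and of slide effects were chosen only after the result was seen. Those of variants under single probes, of differences present whatever the treatment and of other splits of the samples were chosen before.

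The library labelled KO saline replicate 1 lay far from the other 5 of its group on both response scores (0.885 at 6 h and 0.693 at 20 h, others 0.0097 to 0.108 on the latter) and in log2 signal of Tnf (0.73, others −6.03 to −4.37), Il6 (0.98), Il1b (4.39), Cxcl1 (7.10) and Vegfa (4.12). The library labelled KO LPS 6 h replicate 1 lay far from its group on the same scores (0.127 and 0.121, others 0.896 to 0.976 and 0.618 to 0.701) and in Tnf (−5.16, others 0.12 to 0.73), Il6 (−3.93) and Il1b (−1.35). Of 71 groups of values tested in this way 18 held such a sample, where chance gives about 1 in 20.

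For this pair, an effect of the whole slide is argued against by the other arrays on the slide that holds both. WT LPS 20 h replicate 2 and KO LPS 20 h replicate 2 lay 1.72 and 0.26 SD from the rest of their own groups on the 6 h score. These are the only other arrays there, so the argument is weak. Scan date was not tested beyond that slide. An exchange of the 2 libraries is a candidate explanation: 2 of 2 correlated across genes with the other group (r = 0.646 and 0.652) and not with their own (r = −0.431 and −0.404), although genes are not independent replicates. Mice that truly responded in this way, or that received another injection than the label gives, stay open and were not tested. No label was changed.

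The genes called between genotypes on saline form a second pattern, 65 in number. With slide as a block 33 of them (50.8%, 95% interval 38.1 to 63.4) kept call and sign. That interval lay above the bound for slide effects as the whole cause, which was chosen after the result was seen. The other 32 kept their sign but lost the call, as the median size went from 1.98 to 1.94 while its median SE rose from 0.43 to 0.49. The intervals here and below treat genes or probes as independent, so they do not measure the spread between mice or slides. The argument against slide effects as the whole cause is therefore weak. Donor DNA next to E2f1 as the whole cause is argued against by the 2 of 65 called genes (3.08%, interval 0.375 to 10.68) that lay within 20 Mb of it. Sequence variants under single probes (20 of 28 other probes, 71.4%, interval 51.3 to 86.8, moved the same way) and differences present whatever the treatment (52 of 65, 80%, interval 68.2 to 88.9, had the same sign between the 20 h groups, and 58 of 65, 89.2%, between the 6 h groups, for which no bound had been set) stay open, as both intervals span a bound set in advance. An effect of E2F1 loss itself was not separated from other differences between the mouse lines.

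The library labelled KO LPS 20 h replicate 4 lay far from its group on the 20 h score (0.355, others 0.960 to 1.06), in Il6 (−2.20, others −0.23 to 0.05) and in Cyp7a1 (0.47, others −6.59 to −4.25). WT saline replicate 5 did so on the 6 h score (0.085, others −0.0273 to 9.2e-05). Cyp7a1 stood apart in WT LPS 6 h replicate 3 (−3.29) and WT LPS 20 h replicate 4 (−3.12).

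Genes whose response to LPS differed between genotypes by the interaction test were, at 6 h, Tbc1d2 (2.33), Rab40c (1.34), Gtlf3b (1.87), Chst12 (2.64), Tob1 (2.38) and Dedd2 (2.89), with a more positive response in knockouts, and Zfp296 (−2.62), Dll1 (−2.77), Apobec3 (−3.23), Ltbp1 (−2.82), Zufsp (−2.77) and Tanc1 (−1.60), with a more negative one. At 20 h they were Sorl1 (3.40), Fras1 (2.62), Man2a2 (1.38) and Adamts13 (−4.99). All but Man2a2 lay near background in at least 1 group, so their sizes are not exact.

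Other splits of the samples were drawn 100 times, or all 35 for the genotypes at 6 h, the real one included. The real split called the most genes for the genotypes on saline (65, highest other 5) and at 6 h (242, highest other 6). So it did for wild type at 6 h (5470, 1637), at 20 h (7030, 3885) and between the times (6578, 2931). It also did for the interaction at 6 h (24, 12). This argues against chance, although no share could be under 1 in 100 (1 in 35 for the genotypes at 6 h). For knockouts at 20 h (5053, highest other 7273), between their times (2992, highest other 3226) and for the interaction at 20 h (8, highest other 512), 2 splits were as large. This stayed under the share set in advance, but another split called more genes than the real one, so chance is not firmly excluded. The shares were not adjusted over the 11 comparisons. Chance cannot be excluded for the genotypes at 20 h (62 genes, highest other 648, 8 splits as large) or for knockouts at 6 h (502, highest other 6668, 11 splits as large). The highest splits for knockouts at 6 h and for the genotypes and the interaction at 20 h called several times the real number, which points to a structure of the samples. The first of these exchanges exactly KO saline replicate 1 and KO LPS 6 h replicate 1, and the other two move neither. The highest one for knockouts at 20 h moves KO saline replicate 1 and KO LPS 20 h replicate 4, and that between the knockout times moves KO LPS 6 h replicate 1 and KO LPS 20 h replicate 6.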

How the results depend on the processing

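Leaving out the 2 knockout libraries that stood apart was the alternative chosen only after the result was seen. It gave 100 genes between genotypes at 20 h and 5597 for knockouts at 6 h. For knockouts at 6 h the group means changed as well as the spread, the 20 h groups held neither library, and the cause was not tested.

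Of the counts and odds ratios recomputed under each alternative, 318 were taken as unchanged and 83 counts moved by over 1.5-fold. Counts were taken as unchanged within 1.5-fold, and odds ratios where Fisher's exact p stayed on the same side of 0.05, whatever their size. Of the single genes and the numbers of called list members, 40465 counted as unchanged, 1644 lost and 369 gained a call, 663 numbers moved by over 1.5-fold, and 3 reversed. A gene uncalled in the fit of all arrays counted as unchanged wherever its sign turned, so only called genes could reverse. Lists were compared by their number of called members within 1.5-fold, so a turn in the direction of a list was not counted. The reversed ones are Mical3 in knockouts at 6 h, at 0.042 with normexp and quantile normalization, 0.059 with the deposited processed values and 0.09 with the stricter filter, where another of its probes stood for the gene.

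An adjusted p under 0.01, stricter by construction, gave 25, 44 and 20 genes between genotypes on saline, at 6 h and at 20 h, 3482 for wild type at 6 h, and 1 and 2887 for knockouts at 6 h and 20 h. It gave 4326 and 1379 between the times in wild type and knockouts, and 5 and 4 for the interactions at 6 h and 20 h. Array weights gave 213, 1199 and 188 between genotypes, 8013 and 7840 for knockouts, 6983 between their times, and 449 and 70 for the interactions. With only the groups compared, and so fewer arrays for the spread, limma called 7 and 25 genes between genotypes at 6 h and 20 h, 0 (2651 at an unadjusted p under 0.05) and 3065 for knockouts at 6 h and 20 h, and 312 between their times.

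Slide as a block gave 39, 62 and 28 between genotypes, 0 for knockouts at 6 h (3911 unadjusted) and 7 and 1 for the interactions, and scan date as a block 38 for the interaction at 6 h. The replicate block, although shared numbers did not pair arrays (mean r −0.00085 against −0.0012 for other numbers), gave 1 for knockouts at 6 h and 4 for the interaction at 20 h. Without a filter, with more genes tested, there were 116 between genotypes at 6 h, 2 for knockouts at 6 h and 4 for the interaction at 20 h, and with the stricter filter 781 for knockouts at 6 h. Normexp with quantile normalization gave 1 for knockouts at 6 h, median centring and quantile normalization 5 each for the interaction at 20 h, and the deposited processed values 12 and 1 for the interactions. Apart from those named, the cause was not tested.

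With single arrays left out, the counts ranged from 37 to 64 between genotypes on saline, 77 to 185 at 6 h and 33 to 85 at 20 h, with the lowest without WT saline replicate 1, WT LPS 6 h replicate 1 and KO LPS 20 h replicate 3. For wild type they ranged from 4339 to 5233 at 6 h, 6139 to 7335 at 20 h and 5560 to 6499 between the times. For knockouts they ranged from 0 (limma, 2966 at an unadjusted p under 0.05, without KO LPS 6 h replicate 2) to 3885 (without KO LPS 6 h replicate 1) at 6 h, 4071 to 6457 at 20 h and 1802 to 4009 between the times. The interactions ranged from 8 to 29 at 6 h and from 4 to 14 at 20 h. The odds ratio for saline calls near E2f1 ranged from 0.978 (without WT saline replicate 5) to 3.13 (without KO saline replicate 1), and on all of chromosome 2 from 0.456 to 1.26.

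Limits remain: a covariate for sex was not run, the saline mice of the 6 h comparison are labelled 20 h, genes dim relative to the array background give only bounds, and the knockout groups at 6 h rest on 4 arrays.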

Other observations

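In wild type at 20 h several groups of genes moved in both directions without passing as sets. Fatty acid oxidation had 5 rises and 9 falls among 24 genes, also adjusted over the list alone (adjusted p = 0.284), with the pyruvate dehydrogenase kinase Pdk4 at 5.03 ± 0.91 (log2 change and SE) and the hormone Fgf21 at 2.79 ± 1.09. Of 18 clock genes 4 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.428), Per1 by 2.12 and Nfil3 by 2.09, with Dbp at −3.32 ± 0.76. Of 18 oxidative stress genes 4 rose and 6 fell (4 and 7 adjusted over the list alone; adjusted p = 0.705), catalase Cat with −3.27 ± 0.38 and Gpx3 with 2.48. Of 21 angiogenesis genes 4 rose and 6 fell (4 and 8 adjusted over the list alone; adjusted p = 0.94), the VEGF receptor Kdr with −3.64 ± 0.84, Hif1a with 2.67 and Angpt2 with 2.47.

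Granzymes Gzmb (3.52 ± 0.68) and Gzma (2.85 ± 0.39) were among 5 rises of 18 T and NK cell markers in wild type at 20 h (adjusted p = 0.105). The antigen-presentation regulator Ciita (−1.81) and H2-Oa (−2.16) were the 2 falls of 8 class II genes (adjusted p = 0.13). Of 21 G2/M genes 4 fell, Cenpa by 2.19 (adjusted p = 0.12). Of 13 E2F and retinoblastoma family genes 3 rose and 3 fell, E2f8 by 1.30 and Rbl2 with −2.03 ± 0.37 (adjusted p = 0.705). The surfactant genes Sftpa1 (4.52 ± 0.59) and Sftpd (3.08 ± 0.67) were the 2 rises of 6 lung epithelial markers (adjusted p = 0.0879). Counts adjusted over the list alone equalled those given here.

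In knockouts at 20 h, p53 and apoptosis genes rose in 12 of 29 and fell in 1 (13 and 2 adjusted over the list alone; median 1.44, adjusted p = 5.53e-05, and adjusted p = 0.508 with an estimated correlation), Cdkn1a by 3.99 ± 0.77. Urea cycle and amino acid genes fell in 16 of 23 and rose in 2, also adjusted over the list alone (median −1.27, adjusted p = 3.03e-07, and adjusted p = 0.169 with an estimated correlation). The Kupffer cell markers Cd163 (−4.30 ± 0.93) and Vsig4 (−3.91 ± 0.59) were among 7 falls and 3 rises of 19, also adjusted over the list alone (adjusted p = 0.207). The stellate cell gene Colec11 (−3.74 ± 0.44) was among 9 falls and 3 rises of 17 (10 and 3 adjusted over the list alone; adjusted p = 0.0302, and adjusted p = 0.533 with an estimated correlation).

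The genes called with the same sign between genotypes on saline, at 6 h and at 20 h were 5033411D12Rik (−2.89, −3.58 and −2.94), AK139880 (−2.01, −2.48 and −2.67) and the transcript NAP102495-1 (−2.16, −2.69 and −2.56), on chromosomes 13, 19 and 17. Within 20 Mb of E2f1, AK035497 (−1.70) was called on saline beside Rprd1b, and Pdrg1 (1.66), Zswim3 (1.73), Serinc3 (1.35), 2810408M09Rik (1.03) and Blcap (0.85) at 6 h. These genes were chosen after their values were seen.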
